A study of Mus musculus with 6 samples.

How the data were processed

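RNA was sequenced from alveolar macrophages of control mice (Hdac3 floxed, 3 libraries) and of mice with Hdac3 deleted by a Cd11c-driven Cre (3 libraries). Per the labels' protocols, total RNA was extracted with Trizol and libraries followed a standard BGI procedure. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries. Per the submitters' processing notes the tools were Bowtie2 and RSEM, with no versions given, and the build was mm10. Strand handling, adapter removal and quality filters are not given in the sources used here.

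The authors deposited gene-level FPKM (fragments scaled by transcript length and by mapped fragments) with 2 decimals, 1 column per library, per the file headers, and counts were not used here. The table lists 18392 genes by Entrez ID and symbol, and no listed gene was at 0 in all 6 libraries. For 24 genes whose symbols had been turned into dates, the symbol was restored through the Entrez ID. Of the gene IDs, 18342 matched the reference annotation (RefSeq genes on GRCm38.p6, the assembly that mm10 corresponds to) and 50 did not. Coordinates come from that annotation.

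FPKM keep no sequencing depth. The relative depth was estimated from what 1 read is worth in genes with 1 listed transcript and low expression, between 0.4 and 3 FPKM, and lay between 97% and 105% of that of the first control library. The absolute depth is unknown, so no counting interval or detection floor is given. Pearson correlations of log2(FPKM + 1) between libraries of 1 group, taken across genes, which are not independent replicates, were 0.992 to 0.995 for controls and 0.995 for knockouts, and 0.967 to 0.973 between groups.

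Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended and robust empirical Bayes variance, for 10847 genes with a mean of at least 1 FPKM over the 6 libraries. The test was two-sided with genotype as the only term, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Because of the added 1 FPKM, log2 changes understate the changes of genes of low expression. FPKM are relative to each library's total, so genes that take a larger share lower the values of the rest. Each count is therefore given also after scaling by the trimmed mean of M values (TMM), with 30% of the log ratios and 5% of the mean levels trimmed at each end. The factors were computed here in R from the FPKM matrix with the published formula. The plan fixed beforehand named the edgeR function for this step, which was not used because the analysis environment offers edgeR only for tables of counts.

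On simulated data for knockout against control, with 200 of 11017 genes changed, limma recovered 100% of 1.5-fold and 97% of 2-fold changes, and 3.9% of its calls were false. In another simulation the 10 most abundant genes were also raised 4-fold in knockouts and libraries rescaled to 1 sum. There 98.4% of calls were false without scaling and 10.2% after TMM scaling, with calls of the raised genes counted as false. The unchanged genes had a median log2 change of -0.46 before that scaling. Only 200 genes were changed besides those 10, while limma called 7570 of 10847 genes in the data. These shares therefore do not carry over to the data.

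Gene lists were fixed before the data were examined: 30 lists with 977 entries for macrophage identity and regulators, metabolism, activation, stress and other cell types that a lung sort could hold. Of these, 28 with at least 5 tested members were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists), again with an estimated correlation, and with fry, which asks whether the members of a list move on balance one way. By fry 3 lists were higher and 18 lower in knockouts as deposited, and 11 higher and 9 lower after TMM scaling, at an adjusted p under 0.05. Camera compares a list with the other tested genes, so a rise means a rise relative to the median shift. With an estimated correlation none of the 13 lists called by camera kept its call, the smallest adjusted p being 0.35. Nor did any of the 13 called after TMM scaling, the smallest being 0.63. The lists of lipid handling and neutrophils lost their calls too, although their estimated correlations were 0.016 and -0.049 beside the preset of 0.01. In this setting camera also tests on the few residual degrees of freedom of 6 libraries. A lost call therefore does not show that correlation between members accounts for it. Relative to all tested genes, median, mean and test differed in sign for the lists of alveolar macrophage identity, differentiation regulators, p53 targets, interstitial macrophages, dendritic cells and erythroid cells.

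The rule for named genes was also fixed before the data were examined: Hdac3; the 12 largest rises and 12 largest falls among called genes with at least 5 FPKM in the higher group and no overlap between groups, leaving out predicted genes; in each list up to 4 called members with the smallest adjusted p, or the 2 most abundant where none was called; and all sex-linked, HDAC and corepressor genes. Some genes picked by this rule are not reported here. Genes named outside it are said to have been chosen after their values were seen. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, TMM scaling, quantile normalization, rescaling to TPM, array weights, no trend, other thresholds, the replicate number as a block and each library left out. Scaling without the 50 most abundant genes and TMM scaling with an estimated correlation were added after the data were seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.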

Results

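Gene expression was measured by RNA sequencing in alveolar macrophages, the resident phagocytes of the air spaces, which were purified from dissociated mouse lungs by fluorescence-activated sorting. The mice were C57BL/6 animals 6 weeks of age. Control libraries came from mice with both Hdac3 alleles floxed, and knockout libraries from floxed mice that also carried a Cre recombinase driven by the promoter of Cd11c (Itgax), with 3 libraries in each group. Hdac3 is a histone deacetylase and the catalytic subunit of nuclear corepressor complexes. The deposited table holds gene-level FPKM for 18392 genes, whose sum was 462253 to 468193 per control library and 490080 to 504966 per knockout library. Between 10938 and 11077 genes reached 1 FPKM in a control library and between 10393 and 10434 in a knockout library. Values below are mean ± SD in FPKM (n = 3 per group), control first, with the log2 change of FPKM + 1 from knockout minus control.

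Hdac3 (Entrez gene 15183, chromosome 18, 37936971 to 37955015 in GRCm38) fell from 18.2 ± 1.53 to 4.46 ± 0.547 FPKM. The log2 change was -1.81 (SE 0.09; limma adjusted p = 6.8e-07) and -1.48 after TMM scaling. The 3 control libraries read 17.7, 19.9 and 16.9 FPKM and the 3 knockout libraries 4.36, 5.05 and 3.97 FPKM. A gene-level value also counts reads from exons outside the deleted part, which the labels do not name.

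The comparison asks which transcripts differ in alveolar macrophages when Hdac3 is deleted. The secreted glycoprotein gene Fstl1 had the largest rise in log2 change among the tested genes, from 1.21 ± 0.554 to 142 ± 25.8 FPKM (log2 change 6.03, 6.31 after TMM; limma adjusted p = 7.2e-06). Mfge8, whose product bridges apoptotic cells to phagocytes, rose from 6.31 ± 1.37 to 123 ± 5.73 FPKM (log2 change 4.10, 4.45 after TMM). Itgam, the integrin alpha chain of complement receptor 3, rose from 1.20 ± 0.117 to 30.6 ± 0.974 FPKM (log2 change 3.85, 4.13 after TMM). Itgam lies beside Itgax on chromosome 7, and whether the Cre transgene, carried by the knockout mice alone, adds transcripts of Itgam was not tested. The neuropeptide gene Gal fell from 38.2 ± 3.72 to 0.303 ± 0.200 FPKM (log2 change -4.92, -4.69 after TMM). Ear1, an eosinophil-associated ribonuclease gene, fell from 979.7 ± 57.8 to 31.8 ± 2.49 FPKM (log2 change -4.90, -4.53 after TMM). Fcgr2b, the inhibitory Fc gamma receptor, fell from 148 ± 16.9 to 4.35 ± 0.749 FPKM (log2 change -4.80, -4.46 after TMM). Fibronectin (Fn1) fell from 223 ± 47.8 to 7.74 ± 0.317 FPKM (log2 change -4.65, -4.30 after TMM). In the other large rises the knockout means were 583 ± 9.94 FPKM for the chemokine Ccl9, 255 ± 11.7 for Ear6, 126 ± 6.01 for the cyclooxygenase Ptgs1, 99.1 ± 8.93 for the prostacyclin receptor Ptgir, 422 ± 38.7 for Wfdc17, 28.4 ± 0.580 for Syt8, 27.2 ± 6.03 for the phospholipase Pla2g7, 12.5 ± 1.93 for the fatty acid binding protein Fabp7 and 16.1 ± 0.272 for Lrrc27. Their control means were 35.3 ± 6.98, 14.9 ± 0.707, 7.17 ± 0.0917, 5.75 ± 0.679, 30.8 ± 2.65, 1.30 ± 0.212, 0.707 ± 0.240, 0.220 ± 0.140 and 0.987 ± 0.223 FPKM in the same order. In the other large falls, the neutrophil-attracting chemokine Cxcl2 went from 353 ± 130.1 to 13.2 ± 3.82 FPKM. The transcription factor Egr1 fell from 94.9 ± 34.4 to 4.80 ± 0.986 FPKM. The peroxisomal thiolase Acaa1b fell from 137 ± 30.9 to 9.70 ± 2.35 FPKM. Emb, Cpne5, Epcam, Flt1 and L1cam had control means of 30.1 ± 4.19, 37.0 ± 4.63, 17.3 ± 2.25, 29.7 ± 3.49 and 29.6 ± 6.10 FPKM and knockout means of 0.580 ± 0.0436, 1.07 ± 0.215, 0.0700 ± 0.0693, 0.920 ± 0.0954 and 1.46 ± 0.0833. Ear1, Ear2 and Ear6 are related in sequence, so the split of reads between them is uncertain.

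**Figure D1:**
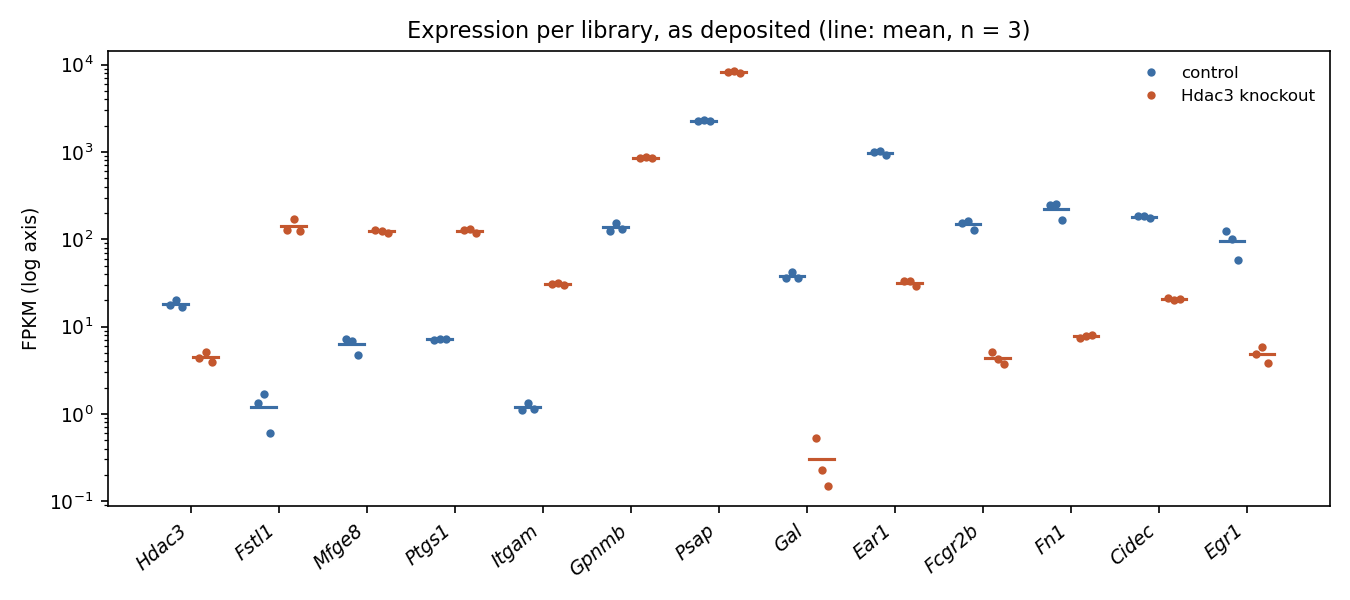
FPKM per library on a log axis for Hdac3 and 12 genes named in the text, with 3 control libraries in blue, 3 knockout libraries in orange and a line at each group's mean. Hdac3 lies at 16.9 to 19.9 FPKM in the controls and 3.97 to 5.05 in the knockouts. The groups do not overlap for any gene drawn, which the rule required of the largest rises and falls.

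Across 10847 genes with a mean of at least 1 FPKM, 7570 changed at a limma adjusted p under 0.05, of which 1194 were higher and 6376 lower in knockouts as deposited, against 3248 higher and 2808 lower of 6056 changed genes after TMM scaling. The 10 most abundant genes of a library held 13.2 to 13.9% of the FPKM sum in controls and 25.5 to 26.8% in knockouts, and the median log2 change of the tested genes was -0.31 as deposited and 0.02 after TMM scaling. Directions below are therefore given under both scalings. All 1194 higher genes were also higher after TMM scaling, and 2808 of the lower genes were also lower, while 160 genes were lower as deposited and higher after TMM scaling. TMM scaling divided control libraries by 1.13 to 1.15 and knockout libraries by 0.87 to 0.88, which raised every log2 change. Rises kept after it thus follow from the scaling and are no separate support. At least 2-fold changes were called for 1102 genes, 244 higher and 858 lower, and for 875 after TMM scaling, 430 higher and 445 lower.

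**Figure D2:**
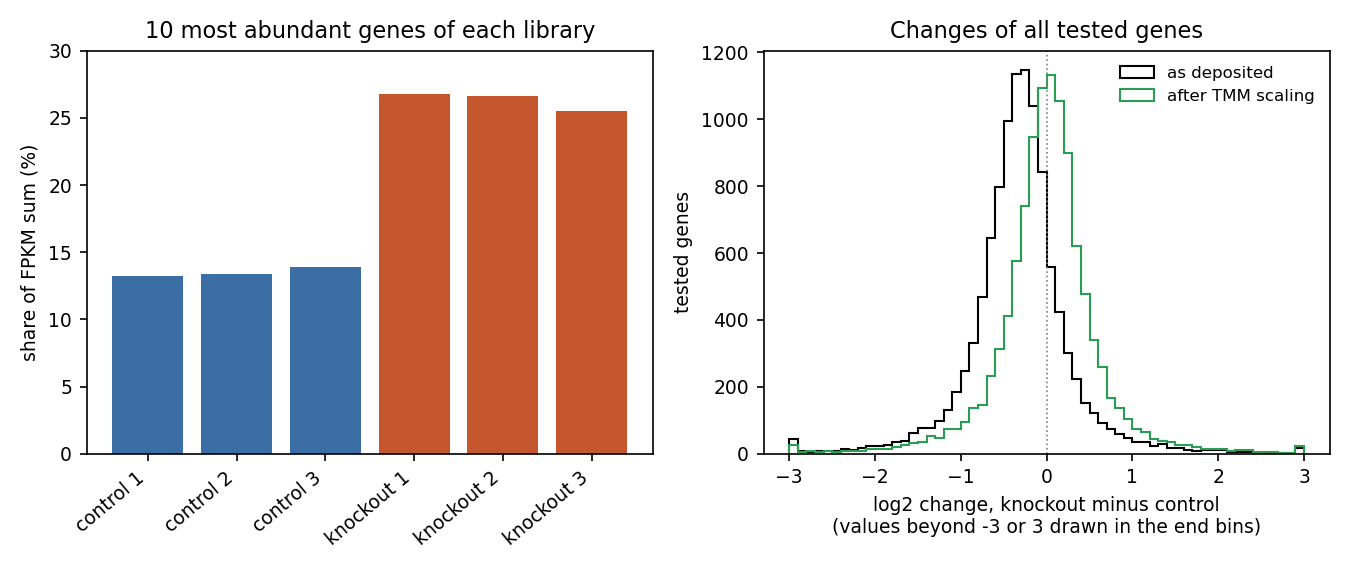
Left, the share of the FPKM sum held by the 10 most abundant genes of each library, in percent, with controls in blue and knockouts in orange. Right, the number of tested genes by log2 change in bins of 0.1, with the median at -0.31 as deposited (black) and 0.02 after TMM scaling (green).

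Among the deacetylases other than Hdac3, Hdac9 fell from 3.03 ± 0.0961 to 0.550 ± 0.0755 FPKM (log2 change -1.38, -1.17 after TMM). Hdac5 fell from 21.6 ± 0.355 to 9.55 ± 0.911 FPKM (log2 change -1.10, -0.75 after TMM). Hdac10 rose from 1.62 ± 0.104 to 3.01 ± 0.487 FPKM (log2 change 0.61, 0.87 after TMM). In the HDAC and corepressor list, 3 of 17 tested members rose and 12 fell, against 5 rose and 6 fell after TMM scaling. The other 2 were not called, and adjusted over the list alone the same counts were called. By camera the list had adjusted p = 0.90. Sin3a, the scaffold of another deacetylase complex, fell from 15.6 ± 0.540 to 7.01 ± 0.249 FPKM (log2 change -1.05, -0.71 after TMM), and Hdac1 and Ncor1 fell less, with log2 changes of -0.56 and -0.64 as deposited, -0.20 and -0.28 after TMM. Tbl1xr1 and Hdac4 rose (log2 changes 0.56 and 0.34 as deposited, 0.91 and 0.68 after TMM), and Tbl1x was not called as deposited (log2 changes 0.10 as deposited, 0.45 after TMM) but rose after TMM scaling. Gps2, Hdac6 and Hdac8 fell as deposited (log2 changes -0.43, -0.33 and -0.53 as deposited, -0.06, -0.01 and -0.27 after TMM) and were not called after TMM scaling, and neither were Hdac2, Rcor1 and Mta2, whose log2 changes turned from -0.28, -0.25 and -0.25 to 0.07, 0.10 and 0.12. Hdac7 and Hdac11 stayed under the level tested. Xist, expressed from the inactive X chromosome, stood at 68.1 ± 1.46 and 64.0 ± 4.12 FPKM in the 2 groups and was not called as deposited (log2 change -0.09), but rose after TMM scaling (log2 change 0.28, limma adjusted p = 0.0036). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty did not exceed 0.07 FPKM in any library, nor did Tsix.

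Lysosomal genes moved in both directions. Psap, the precursor of sphingolipid activator proteins, rose from 2289 ± 51.5 to 8252 ± 121 FPKM (log2 change 1.85, 2.23 after TMM). The protease Ctsd rose from 3650 ± 162 to 10138 ± 394 FPKM (log2 change 1.47, 1.85 after TMM). The protease Ctsb rose from 295 ± 10.2 to 851 ± 31.6 FPKM (log2 change 1.52, 1.90 after TMM). Gpnmb, a glycoprotein of lysosomes and melanosomes, rose from 137 ± 14.8 to 857 ± 21.7 FPKM (log2 change 2.65, 3.02 after TMM). In the lysosome list, 22 of 53 tested members rose and 17 fell, against 38 rose and 6 fell after TMM scaling. The other 14 were not called, and adjusted over the list alone 23 rose and 18 fell. The list had camera adjusted p = 1.9e-08, or adjusted p = 0.41 with an estimated correlation. The ferritin genes Fth1 and Ftl1 and the peroxiredoxin gene Prdx1 rose. Fth1 went from 7640 ± 313 to 22714 ± 1237 FPKM (log2 change 1.57, 1.95 after TMM). Ftl1 rose from 6790 ± 358 to 15578 ± 847 FPKM (log2 change 1.20, 1.58 after TMM). Prdx1 rose from 466 ± 12.2 to 1406 ± 60.3 FPKM (log2 change 1.59, 1.97 after TMM). Mgst3 fell from 63.0 ± 6.25 to 19.5 ± 0.727 FPKM (log2 change -1.64, -1.27 after TMM). In the NRF2 and oxidative stress list, 9 of 22 tested members rose and 6 fell, against 14 rose and 3 fell after TMM scaling. The other 7 were not called, and adjusted over the list alone the same counts were called. For this list camera gave adjusted p = 7.0e-05, or adjusted p = 0.38 with an estimated correlation.

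Markers of alveolar macrophages moved in both directions. Ear1, Ear2, the lipid droplet gene Cidec and Flt1 fell, Ear2 from 2742 ± 131 to 506 ± 8.73 FPKM (log2 change -2.43, -2.06 after TMM). Cidec fell from 181 ± 3.98 to 20.7 ± 0.720 FPKM (log2 change -3.07, -2.70 after TMM). In the identity list, 15 of 32 tested members rose and 13 fell, against 17 rose and 13 fell after TMM scaling. The other 4 were not called, and adjusted over the list alone 15 rose and 14 fell. The camera test of the list gave adjusted p = 0.0067, or adjusted p = 0.51 with an estimated correlation, and adjusted p = 0.61 after TMM scaling. Car4 and Itgax, chosen after their values were seen, rose from 407 ± 119 to 1749 ± 264 FPKM (log2 change 2.14, 2.51 after TMM) and from 436 ± 11.8 to 852 ± 20.2 FPKM (log2 change 0.97, 1.34 after TMM), and Siglecf, also chosen after, stood at 234 ± 3.93 and 226 ± 9.62 FPKM and was not called as deposited but rose after TMM scaling (log2 changes -0.05 as deposited, 0.32 after TMM). Relative to all tested genes the list's median was 0.43 higher and its mean 0.07 lower, while camera ranked it upward. Among differentiation regulators, Bhlhe41 rose from 18.2 ± 0.947 to 41.3 ± 3.08 FPKM (log2 change 1.13, 1.5 after TMM). Klf4 fell from 95.2 ± 8.39 to 33.8 ± 2.09 FPKM (log2 change -1.47, -1.10 after TMM). Zeb1 fell from 2.93 ± 0.147 to 0.413 ± 0.127 FPKM (log2 change -1.48, -1.28 after TMM). The TGF-beta receptor Tgfbr1 fell from 98.2 ± 2.75 to 56.4 ± 3.88 FPKM (log2 change -0.79, -0.42 after TMM). In this list, 6 of 26 tested members rose and 16 fell, against 10 rose and 9 fell after TMM scaling, which turned the balance. The other 4 were not called, and adjusted over the list alone the same counts were called. In the camera test adjusted p = 0.79 was obtained. The nuclear receptor Pparg, chosen after its values were seen, fell from 129 ± 4.63 to 74.0 ± 6.40 FPKM (log2 change -0.80, -0.43 after TMM).

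Genes of lipid handling moved in both directions. The scavenger receptor Msr1 rose from 23.5 ± 1.65 to 69.5 ± 4.44 FPKM (log2 change 1.52, 1.89 after TMM). The lipid droplet coat gene Plin2 rose from 693 ± 54.8 to 1666 ± 102 FPKM (log2 change 1.26, 1.64 after TMM). Dgat2, an enzyme of triglyceride synthesis, fell from 48.2 ± 6.52 to 6.56 ± 0.495 FPKM (log2 change -2.70, -2.35 after TMM) together with Cidec. In the list of lipid uptake, storage and efflux, 15 of 37 tested members rose and 16 fell, against 21 rose and 9 fell of 38 after TMM scaling, which turned the balance. The other 6 were not called, and adjusted over the list alone the same counts were called. Tested with camera, the list had adjusted p = 7.7e-04, or adjusted p = 0.35 with an estimated correlation. In cholesterol synthesis, Cyp51 fell from 20.9 ± 0.439 to 8.98 ± 1.40 FPKM (log2 change -1.15, -0.80 after TMM). Nsdhl fell from 14.2 ± 0.650 to 7.97 ± 0.446 FPKM (log2 change -0.76, -0.42 after TMM). In that list, 1 of 25 tested members rose and 23 fell, against 1 rose and 19 fell after TMM scaling. The other 1 was not called, and adjusted over the list alone the same counts were called. Camera gave the list adjusted p = 0.0094, or adjusted p = 0.82 with an estimated correlation. The 1 member that rose, Dhcr7, was named after its values were seen and went from 23.7 ± 1.69 to 39.2 ± 2.83 FPKM (log2 change 0.70, 1.06 after TMM).

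In energy metabolism, the glycolytic genes Pgam1 and Pgk1 rose, from 73.8 ± 8.41 to 215 ± 12.4 FPKM (log2 change 1.53, 1.91 after TMM) and from 74.0 ± 3.45 to 151 ± 8.76 FPKM (log2 change 1.02, 1.39 after TMM), and the regulators of fructose bisphosphate Pfkfb3 and Pfkfb4 fell, with log2 changes of -1.41 and -0.88 as deposited, -1.07 and -0.51 after TMM. In the glycolysis list, 10 of 21 tested members rose and 6 fell, against 14 rose and 4 fell after TMM scaling. The other 5 were not called, and adjusted over the list alone the same counts were called. By camera the list had adjusted p = 2.2e-04, or adjusted p = 0.56 with an estimated correlation. In oxidative phosphorylation, 2 of 77 tested members rose and 42 fell, against 38 rose and 1 fell after TMM scaling, which turned the balance. The other 33 were not called, and adjusted over the list alone 2 rose and 39 fell. The list had camera adjusted p = 0.90, and adjusted p = 6.2e-04 after TMM scaling, or adjusted p = 0.74 there with an estimated correlation. Sdhd and Cox5a rose under both scalings (log2 changes 0.64 and 0.55 as deposited, 1.01 and 0.92 after TMM), Ndufs8 fell under both (log2 changes -1.01 as deposited, -0.64 after TMM), and Uqcrfs1 fell as deposited only (log2 changes -0.47 as deposited, -0.10 after TMM). In fatty acid oxidation, 6 of 38 tested members rose and 22 fell, against 13 rose and 10 fell after TMM scaling, which turned the balance. The other 10 were not called, and adjusted over the list alone the same counts were called. For this list camera gave adjusted p = 0.99. Its transport enzyme gene Cpt1a fell from 128 ± 3.28 to 82.6 ± 0.231 FPKM (log2 change -0.63, -0.25 after TMM). Acaa1a fell from 98.2 ± 3.65 to 56.4 ± 1.94 FPKM (log2 change -0.79, -0.42 after TMM). Ucp2 fell from 1639 ± 81.0 to 949.9 ± 78.7 FPKM (log2 change -0.79, -0.41 after TMM).

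Phagocytic receptors changed in both directions. Itgam and Msr1 rose, as did the complement receptor C3ar1, from 0.200 ± 0.0608 to 4.73 ± 0.0458 FPKM (log2 change 2.26, 2.44 after TMM), and Fcgr2b fell. In the list of phagocytosis and scavenger receptors, 18 of 33 tested members rose and 12 fell, against 21 rose and 10 fell after TMM scaling. The other 3 were not called, and adjusted over the list alone 20 rose and 12 fell. The camera test of the list gave adjusted p = 2.3e-07, or adjusted p = 0.35 with an estimated correlation. The matrix proteases Mmp12 and Mmp19 rose, Mmp12 from 2.90 ± 0.369 to 23.9 ± 1.92 FPKM (log2 change 2.68, 3.0 after TMM). Mmp19 rose from 81.2 ± 3.30 to 329 ± 28.1 FPKM (log2 change 2.0, 2.38 after TMM). In the matrix list, 9 of 24 tested members rose and 11 fell, against 10 rose and 6 fell after TMM scaling, which turned the balance. The other 4 were not called, and adjusted over the list alone 9 rose and 12 fell. In the camera test adjusted p = 0.0094 was obtained, or adjusted p = 0.63 with an estimated correlation, and adjusted p = 0.54 after TMM scaling. Of genes linked to alternative activation, Ptgs1 rose and Fn1, Matn2 and Socs2 fell, Matn2 from 38.0 ± 2.35 to 11.7 ± 0.0964 FPKM (log2 change -1.61, -1.26 after TMM). Socs2 fell from 21.0 ± 0.539 to 8.65 ± 0.424 FPKM (log2 change -1.19, -0.84 after TMM). In that list, 8 of 20 tested members rose and 9 fell, against 10 rose and 8 fell after TMM scaling, which turned the balance. The other 3 were not called, and adjusted over the list alone 8 rose and 10 fell. Tested with camera, the list had adjusted p = 0.027, or adjusted p = 0.51 with an estimated correlation, and adjusted p = 0.74 after TMM scaling.

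Among inflammatory genes Nfkb1 fell from 45.0 ± 1.84 to 21.6 ± 0.438 FPKM (log2 change -1.02, -0.66 after TMM). The apoptosis inhibitor Birc3 fell from 22.3 ± 1.23 to 9.18 ± 0.666 FPKM (log2 change -1.19, -0.84 after TMM). Cd83 fell from 46.4 ± 7.04 to 12.9 ± 1.20 FPKM (log2 change -1.77, -1.41 after TMM). The chemokine Ccl5 fell from 11.9 ± 2.49 to 2.32 ± 0.117 FPKM (log2 change -1.94, -1.63 after TMM). In the controls Ccl5, itself in the lymphocyte list, and Cxcl2 kept the library order of the lymphocyte, endothelial and epithelial FPKM sums. In the NF-kB list, 5 of 34 tested members rose and 18 fell, against 9 rose and 16 fell after TMM scaling. The other 11 were not called, and adjusted over the list alone the same counts were called. Camera gave the list adjusted p = 0.90. Of immediate-early genes, Nr4a2 fell from 14.4 ± 4.75 to 0.290 ± 0.105 FPKM (log2 change -3.53, -3.31 after TMM). Btg2 fell from 185 ± 9.77 to 41.1 ± 5.74 FPKM (log2 change -2.15, -1.77 after TMM). Fosl2 fell from 121 ± 14.1 to 48.5 ± 0.494 FPKM (log2 change -1.30, -0.93 after TMM). Klf6 fell from 133 ± 4.41 to 76.2 ± 6.93 FPKM (log2 change -0.79, -0.42 after TMM). In that list, 21 of 29 tested members fell, against 17 fell of 28 after TMM scaling. The other 8 were not called, and adjusted over the list alone the same counts were called. By camera the list had adjusted p = 0.0067, or adjusted p = 0.69 with an estimated correlation. Atf3 fell from 108 ± 20.5 to 19.9 ± 2.84 FPKM (log2 change -2.37, -2.00 after TMM), Nupr1 and Phgdh fell too (log2 changes -0.95 and -0.75 as deposited, -0.59 and -0.38 after TMM), and Xbp1 fell as deposited only (log2 changes -0.53 as deposited, -0.15 after TMM). In the list of the integrated stress and unfolded protein responses, 3 of 27 tested members rose and 11 fell, against 7 rose and 3 fell after TMM scaling, which turned the balance. The other 13 were not called, and adjusted over the list alone 3 rose and 8 fell. The list had camera adjusted p = 0.56. The p53-linked genes Perp and Sesn1 and the cell cycle inhibitor Cdkn1b fell, Perp from 87.9 ± 3.10 to 21.9 ± 2.23 FPKM (log2 change -1.96, -1.59 after TMM), and the log2 changes of Sesn1 and Cdkn1b were -1.18 and -0.89 as deposited, -0.91 and -0.53 after TMM. In that list, 5 of 29 tested members rose and 13 fell, against 12 rose and 9 fell after TMM scaling, which turned the balance. The other 11 were not called, and adjusted over the list alone the same counts were called. For this list camera gave adjusted p = 0.34.

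Among interferon-stimulated genes Oas1g, which shares sequence with Oas1a, rose from 0.690 ± 0.187 to 8.18 ± 2.0 FPKM (log2 change 2.42, 2.66 after TMM). Ifi204 rose from 7.54 ± 1.31 to 23.7 ± 4.47 FPKM (log2 change 1.53, 1.88 after TMM). Phf11b rose from 1.07 ± 0.352 to 3.37 ± 0.200 FPKM (log2 change 1.09, 1.33 after TMM). Gbp2 fell from 9.96 ± 0.333 to 6.08 ± 0.621 FPKM (log2 change -0.63, -0.30 after TMM). In that list, 18 of 45 tested members rose and 12 fell, against 25 rose and 2 fell of 46 after TMM scaling. The other 15 were not called, and adjusted over the list alone the same counts were called. The camera test of the list gave adjusted p = 7.7e-07, or adjusted p = 0.69 with an estimated correlation. Its FPKM sum was 374.7, 360.9 and 382.6 in the control libraries and 481.1, 343.0 and 495.2 in the knockout libraries, so knockout replicate 2 lay below all controls. Without that library the mean difference of the list was 0.93, and without knockout replicate 3 it was 0.60, against 0.75 with all libraries. Among proliferation genes Rrm2, a subunit of ribonucleotide reductase, rose from 15.9 ± 1.93 to 32.0 ± 2.0 FPKM (log2 change 0.97, 1.33 after TMM). Mki67 rose from 19.4 ± 1.15 to 31.3 ± 1.27 FPKM (log2 change 0.67, 1.03 after TMM). Bub1b rose from 25.4 ± 1.69 to 40.7 ± 2.48 FPKM (log2 change 0.66, 1.03 after TMM), and E2f1 fell as deposited only (log2 changes -0.44 as deposited, -0.08 after TMM). In the cell cycle list, 17 of 51 tested members rose and 5 fell, against 33 rose after TMM scaling. The other 29 were not called, and adjusted over the list alone 15 rose and 4 fell. In the camera test adjusted p = 1.9e-08 was obtained, or adjusted p = 0.51 with an estimated correlation. Of genes of MHC class II presentation, H2-DMa fell from 168 ± 5.25 to 60.2 ± 6.77 FPKM (log2 change -1.47, -1.09 after TMM). H2-DMb1 fell from 72.4 ± 3.10 to 41.3 ± 1.79 FPKM (log2 change -0.80, -0.43 after TMM). H2-DMb2 fell from 27.9 ± 3.55 to 9.25 ± 2.22 FPKM (log2 change -1.51, -1.16 after TMM). H2-Oa fell from 4.70 ± 1.01 to 1.98 ± 0.244 FPKM (log2 change -0.92, -0.64 after TMM). In that list, 9 of 11 tested members fell, against 2 rose and 8 fell after TMM scaling. The other 2 were not called, and adjusted over the list alone the same counts were called. Tested with camera, the list had adjusted p = 0.21, and adjusted p = 0.016 after TMM scaling, or adjusted p = 0.71 there with an estimated correlation. Cd74, the invariant chain, chosen after its values were seen, fell from 200.3 ± 88.4 to 44.1 ± 1.68 FPKM (log2 change -2.06, -1.69 after TMM). Its control libraries read 290.1, 197.4 and 113.3 FPKM, the order of the FPKM sums of the lymphocyte list (134, 118.8 and 101), the endothelial list (157.4, 117.4 and 88.0) and the epithelial list (405.8, 258.7 and 185.7). Beside a median log2 change of -1.51 for 9 class II genes, that of 6 B cell markers was -1.29 and that of 13 dendritic cell markers -0.44 as deposited.

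**Figure D3:**
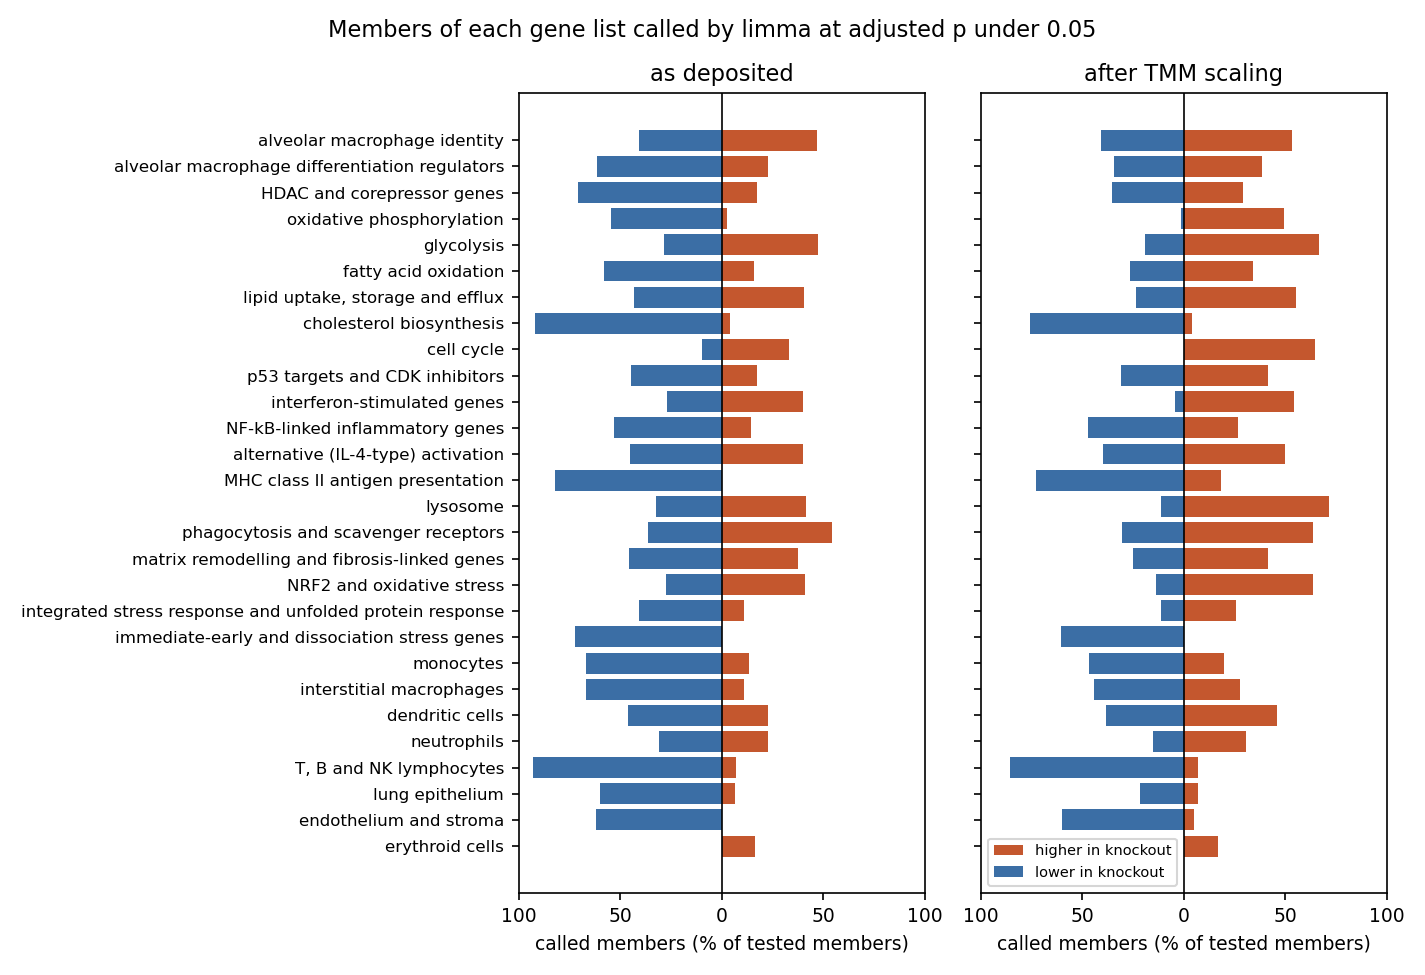
Share of the tested members of each gene list that limma called higher (orange, to the right) or lower (blue, to the left) in knockouts, in percent, as deposited on the left and after TMM scaling on the right. Cholesterol biosynthesis holds 23 lower genes of 25 as deposited and 19 after TMM scaling, while oxidative phosphorylation changes from 42 lower genes of 77 to 38 higher ones.

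Markers of other cell types that a lung sort could hold were examined too. In the lymphocyte list, 1 of 14 tested members rose and 13 fell, against 1 rose and 12 fell after TMM scaling. Adjusted over the list alone the same counts were called. Camera gave the list adjusted p = 0.16, and adjusted p = 0.0027 after TMM scaling, or adjusted p = 0.71 there with an estimated correlation. Gzma and Nkg7 of cytotoxic cells fell (log2 changes -1.60 and -1.30 as deposited, -1.34 and -1.13 after TMM), and Il7r rose from 1.27 ± 0.410 to 6.04 ± 0.745 FPKM (log2 change 1.64, 1.90 after TMM). Among endothelial and stromal markers, 13 of 21 tested members fell, against 1 rose and 12 fell of 20 after TMM scaling. The other 8 were not called, and adjusted over the list alone the same counts were called. By camera the list had adjusted p = 0.32, and adjusted p = 0.0036 after TMM scaling, or adjusted p = 0.74 there with an estimated correlation. Calcrl, Inmt and Gpx3 fell (log2 changes -0.67, -1.35 and -0.73 as deposited, -0.32, -1.14 and -0.49 after TMM), and Kdr, tested as deposited only, fell from 1.77 ± 0.606 to 0.367 ± 0.0666 FPKM. Among lung epithelial markers, 1 of 15 tested members rose and 9 fell, against 1 rose and 3 fell of 14 after TMM scaling. The other 5 were not called, and adjusted over the list alone the same counts were called. The list had camera adjusted p = 0.56. Epcam and Cxcl15 fell under both scalings (for Cxcl15 log2 changes -1.10 as deposited, -0.92 after TMM), and Napsa and Abca3 as deposited only (log2 changes -0.36 and -0.59 as deposited, 0.00 and -0.23 after TMM). The FPKM sum of the epithelial list was 405.8, 258.7 and 185.7 in the control libraries and 99.5, 104.0 and 170.2 in the knockout libraries. In the monocyte list, 2 of 15 tested members rose and 10 fell, against 3 rose and 7 fell after TMM scaling. The other 3 were not called, and adjusted over the list alone the same counts were called. For this list camera gave adjusted p = 0.84. S100a4, Klra2 and Nr4a1 fell (log2 changes -1.77, -1.26 and -2.95 as deposited, -1.50, -0.89 and -2.59 after TMM), and Spn fell as deposited only (log2 changes -0.44 as deposited, -0.09 after TMM). In the list of interstitial macrophages, 2 of 18 tested members rose and 12 fell, against 5 rose and 8 fell after TMM scaling. The other 4 were not called, and adjusted over the list alone the same counts were called. The camera test of the list gave adjusted p = 0.99. Rnase4, Sepp1 and Hpgds fell (log2 changes -2.88, -2.41 and -1.95 as deposited, -2.53, -2.04 and -1.74 after TMM) and Itgam rose. In the dendritic cell list, 3 of 13 tested members rose and 6 fell, against 6 rose and 5 fell after TMM scaling, which turned the balance. The other 4 were not called, and adjusted over the list alone 4 rose and 7 fell. In the camera test adjusted p = 0.56 was obtained. Cd24a rose from 71.4 ± 8.68 to 290.3 ± 12.7 FPKM (log2 change 2.01, 2.39 after TMM), while Batf3, Naaa and Gpr132 fell (log2 changes -2.13, -0.84 and -1.12 as deposited, -1.93, -0.46 and -0.91 after TMM). In the neutrophil list, 3 of 13 tested members rose and 4 fell, against 4 rose and 2 fell after TMM scaling, which turned the balance. The other 6 were not called, and adjusted over the list alone the same counts were called. Tested with camera, the list had adjusted p = 0.035, or adjusted p = 0.41 with an estimated correlation, and adjusted p = 0.41 after TMM scaling. Cxcr1 rose from 9.09 ± 1.56 to 53.6 ± 1.65 FPKM (log2 change 2.45, 2.80 after TMM) and Clec4d rose too (log2 changes 1.65 as deposited, 2.01 after TMM), Trem1 fell (log2 changes -1.32 as deposited, -0.95 after TMM), and Mcemp1 fell as deposited only (log2 changes -0.54 as deposited, -0.16 after TMM). Of the erythroid list 1 of 6 tested members, the globin chaperone Ahsp, rose from 12.7 ± 1.21 to 24.4 ± 3.35 FPKM (log2 change 0.88, 1.24 after TMM), under both scalings and adjusted over the list alone (camera adjusted p = 0.39). The other 5 were not called. The median log2 change of this list was -1.22, and its FPKM sum was 301.5, 240.7 and 53.4 in the control libraries and 54.6, 52.8 and 132.2 in the knockout libraries. In the list of eosinophils, basophils and mast cells only Ear6 reached the level tested.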

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

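Scaling without the 50 most abundant genes and TMM scaling with an estimated correlation were chosen after the data were seen, and the other alternatives before the data were examined. Of 7570 genes called as deposited by limma, 4002 were called with the same sign after TMM scaling and 160 with the opposite sign. The number of higher genes, 1194 as deposited, was 3248 after TMM scaling, 2989 after quantile normalization and 1950 when scaled without the 50 most abundant genes. The number of lower genes, 6376 as deposited, was 2808 after TMM scaling and 2867 after quantile normalization. These 3 settings change the scaling between libraries, by 1 factor per library or, in quantile normalization, by rank. The number of genes changed at least 2-fold, 1102 as deposited, was 707 with a mean of at least 5 FPKM, where fewer genes were tested, and 1752 when rescaled to TPM, which makes the library sums equal, makes the added 1 a smaller share of the values and brings more genes into the test; the cause was not tested. Camera called 13 lists, 8 after quantile normalization, and with an estimated correlation the number was 0, both as deposited and after TMM scaling.

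The other alternatives kept these counts within 1.5 times: the number of changed genes was 7570 with a pseudocount of 0.1, 8784 with no filter, 5678 with a mean of at least 5 FPKM, 8739 as TPM, 7841 with array weights, 7543 with no trend, 6148 at an adjusted p under 0.01 and 8231 at 0.1. The replicate number as a block gave 7373 changed genes, but no label says that the numbers pair the libraries. The deviations of libraries of 1 number from their group means correlated at -0.11, -0.06 and -0.09, against 0.01 to 0.09 for libraries of unlike number. Pairing was thus not seen, but 3 libraries per group are too few to exclude it. With each library left out in turn, between 6879 and 7245 genes changed, 1027 to 1165 were higher, 5780 to 6080 lower and 1039 to 1180 changed at least 2-fold, and 12 to 15 lists were called. The log2 change of Hdac3 was -1.45 to -2.01 over all alternatives and its adjusted p between 1.6e-07 and 1.3e-05.

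After quantile normalization the direction given by camera turned for 2 lists, although their mean differences kept their sign: alveolar macrophage identity had a mean difference of -0.39 (-0.068 as deposited; adjusted p = 0.67) and alternative activation of 0.031 (0.15 as deposited; adjusted p = 0.96). Quantile normalization also ended the calls of glycolysis (adjusted p = 0.093), lipid handling (0.16), phagocytosis (0.085), NRF2 (0.079), matrix genes (0.81) and neutrophils (0.35), and added MHC class II (0.002), lymphocytes (0.0061) and endothelium (0.011). With no filter identity (adjusted p = 0.054) and alternative activation (0.056) lost their calls, and MHC class II (0.045) and lymphocytes (0.0038) gained them. Neutrophils lost theirs with a mean of at least 5 FPKM (adjusted p = 0.11) and with array weights (0.051). Under TMM scaling and quantile normalization in this order, the log2 change turned to 0.072 and 0.073 for Hdac2, 0.118 and 0.016 for Mta2 and 0.097 and 0.122 for Rcor1. It turned to 0.044 for Hdac6 after quantile normalization, and after TMM scaling to 0.0042 for Napsa, 0.32 for Siglecf and 0.28 for Xist. Beyond the scaling itself, the cause was not tested. Without control replicate 3 camera also called the lists of MHC class II (adjusted p = 0.046), lymphocytes (adjusted p = 0.039) and endothelium (adjusted p = 0.046), and no longer called neutrophils (adjusted p = 0.083), nor did it without knockout replicate 2 (adjusted p = 0.1). Hdac2 was no longer called without control replicate 3 or knockout replicate 3 (adjusted p = 0.062 and 0.063), Rcor1 without control replicate 1 or 2 (0.056 and 0.052), and Hdac6 without control replicate 1 or 3 or knockout replicate 1 or 3 (0.059 to 0.11). The absolute depth is unknown, so the precision of genes near 1 FPKM cannot be given.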

Other observations

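The gene families in this part and the genes Pycard and Itgad were chosen after their values were seen, as were the counts by control library order. The tests of the few abundant genes, of RNA per cell, and of the other cell types and 3 of them alone were chosen after too. The same holds for the tests of MHC class II and of heat-shock genes and for the final form of that of silent genes. Genes of eicosanoid metabolism, lipid mediators made from arachidonic acid, moved apart. Ptgs1 and Ptgir were among the largest rises, and Tbxas1, the thromboxane synthase, rose from 96.2 ± 10.4 to 133 ± 10.5 FPKM (log2 change 0.47, 0.84 after TMM). Alox5, which starts the formation of leukotrienes, fell from 126 ± 19.3 to 15.6 ± 1.77 FPKM (log2 change -2.93, -2.57 after TMM). Ltc4s fell from 272 ± 20.4 to 131 ± 9.59 FPKM (log2 change -1.05, -0.68 after TMM). Alox5ap fell from 567 ± 6.44 to 360.2 ± 17.7 FPKM (log2 change -0.65, -0.28 after TMM), and the prostaglandin synthases Ptges and Hpgds fell with log2 changes of -1.08 and -1.95 as deposited, -0.86 and -1.74 after TMM. Of 21 tested enzymes and receptors of this family 5 rose, 13 fell and 3 were not called by limma, against 7 that rose and 7 that fell after TMM scaling. Of all 10847 tested genes 1194 rose and 6376 fell, against 3248 and 2808 of 10817 after TMM scaling. The family was not tested against these shares.

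Chemokine ligands also moved apart. Ccl6 rose from 3193 ± 295 to 9431 ± 494 FPKM (log2 change 1.57, 1.94 after TMM). Ccl2, which attracts monocytes, rose from 9.35 ± 2.96 to 41.6 ± 8.11 FPKM (log2 change 2.07, 2.42 after TMM), besides Ccl9. Cx3cl1 fell from 22.2 ± 0.876 to 3.15 ± 0.412 FPKM (log2 change -2.49, -2.16 after TMM). Cxcl1 fell from 11.0 ± 6.94 to 0.863 ± 0.228 FPKM (log2 change -2.53, -2.27 after TMM), besides Cxcl2. Of 19 tested ligands 5 rose, 10 fell and 4 were not called, against 5 that rose and 8 that fell after TMM scaling. These counts were not tested against the shares of all tested genes given above. Among controls Cxcl1 (18.6, 9.20 and 5.09 FPKM), Cxcl2 (496, 319 and 243 FPKM) and Ccl5 (14.1, 12.4 and 9.20 FPKM) kept the library order of the lymphocyte, endothelial and epithelial sums. So did 7 of the 10 lower ligands, 5 of the 9 lower MHC class II members and 10 of the 21 lower immediate-early members, against 19.4% of all 6376 lower genes. Of the largest falls, Egr1 (125, 102 and 57.6 FPKM), Acaa1b (159, 150 and 102 FPKM) and Cpne5 (40, 39 and 32 FPKM) kept it too. Epcam, itself in the epithelial list, also kept it, while Gal, Ear1, Fcgr2b, Fn1, Emb, Flt1 and L1cam did not. Of the ligands that kept it, Ccl5 and Cxcl15 are themselves in the lymphocyte and epithelial lists. In other lists the lower members kept the order in 9 of 18 for NF-kB, 6 of 12 for interstitial macrophages and 5 of 11 for matrix. The counts were 7 of 16 for lipid handling, 4 of 10 for monocytes and 9 of 23 for cholesterol synthesis. Below 19.4% were the lysosome (0 of 17), oxidative phosphorylation (7 of 42), macrophage identity (2 of 13) and interferon (2 of 12) lists. So were the HDAC and corepressor (1 of 12), glycolysis (0 of 6) and cell cycle (0 of 5) lists. RNA of other cells in the controls may have a part in the falls of genes that kept the order, which was not tested. Around Itgax, whose promoter drives Cre in the knockout mice (chromosome 7, 128129526 to 128150657 in GRCm38), Itgam (128062640 to 128118491) rose (log2 changes 3.85 as deposited, 4.13 after TMM), as did Pycard (log2 changes 1.26 as deposited, 1.61 after TMM), and Itgad fell (log2 changes -1.48 as deposited, -1.28 after TMM).

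Most tested genes were lower in knockouts as deposited, with a median log2 change of -0.31. The 50 most abundant genes held 23.3 to 24.0% of the FPKM sum in controls and 37.4 to 37.8% in knockouts. Rescaling by the other genes moved the median to -0.14, and with 500 genes left out it was -0.05. Such rescaling moves the changes of the remaining genes toward 0 whatever the cause, so these medians do not show what caused the shift. A rise of the abundant genes and less RNA per cell for most genes cannot be told apart. FPKM are relative to each library's total, and the table holds neither spike-in RNA nor cell numbers. An effect of the Hdac3 deletion on RNA content stays open, as untested. The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 7570 called genes, and the highest of the others gave 0.

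Markers of several other cell types were lower in knockouts, although the labels name a sort of alveolar macrophages. An equal loss of all these cells would lower their markers alike, if the markers came from these cells alone. The medians of 7 lists with 109 genes lay between -1.22 for lymphocytes and -0.04 for neutrophils. The mean log2 value of the lymphocyte list minus that of the neutrophil list changed by -0.99 (SD between libraries 0.23 in controls and 0.08 in knockouts). For the 73 markers under 10 FPKM in controls it changed by -1.39 (SD 0.17 and 0.11). These lists did not fall alike, but they were picked as the extremes of the 7 lists. The neutrophil list also holds Cxcr1, which rose from 9.09 to 53.6 FPKM, so the gap need not reflect cell numbers. An equal loss therefore stays open, as do unequal losses. With 3 libraries per group the exact p cannot be under 0.1. The medians of lymphocytes, endothelium and stroma, and epithelium (-1.22, -0.99 and -0.91, 50 genes) were closer. Lymphocytes minus epithelium changed by 0.07 (SD 0.09 and 0.28). Their FPKM sums kept 1 order among controls (exact p of the rank concordance 0.028) but not among knockouts (exact p = 0.94). Few such cells in the knockouts would also leave no shared order there, so its absence does not count against fewer cells. Fewer of these cells cannot be told apart from an effect of the deletion on these transcripts. For the 9 MHC class II genes (median -1.51, interquartile range 0.52), markers of dendritic and B cells together lay 0.67 higher (median -0.84, interquartile range 1.15, 19 genes), which is within their spread. The 6 B cell markers alone had a median of -1.29 (interquartile range 0.16), near that of the class II genes. The 13 dendritic cell markers had one of -0.44 (interquartile range 1.28). The lists were not matched for level, and the added 1 FPKM understates changes of genes of low expression, so near medians need not mean like falls. Among controls Cd74 kept the order of the lymphocyte, endothelial and epithelial sums while H2-DMa (162.8, 166.9 and 173.2 FPKM) and H2-DMb1 (72.1, 75.6 and 69.4 FPKM) did not. Fewer dendritic or B cells and lower class II expression within macrophages cannot be told apart for this reason.

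The 22 immediate-early members of their list had a median log2 change of -1.16 relative to the median gene, and limma called 20 of them lower as deposited and 17 after TMM scaling. More handling stress in the controls would be expected to raise the 7 heat-shock members too, but their median was -0.07 (quartiles -0.16 and 0.07), which argues against stress that acts on both kinds. The list stayed called by camera without each of the 6 libraries, with adjusted p between 0.0015 and 0.014, the highest without knockout replicate 2, which argues against 1 library carrying the difference. With an estimated correlation the list was not called (adjusted p = 0.69). A handling difference that acts on immediate-early genes alone stays open, since the labels give no times of digestion or sorting, as do RNA of other cells in the controls and an effect of the Hdac3 deletion.

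Hdac3 takes part in repression, so a hypothesis was that more genes would be switched on than off without it. Below 0.1 FPKM in each library of 1 group and at least 1 FPKM in each of the other, 8 genes were gained and 13 lost in knockouts, a ratio of 0.62, against 9 and 11 after TMM scaling. The numbers gained were thus not above those lost, which was the bound first set against the hypothesis. A condition on the spread was added after these counts were seen: against a ratio of 1.5 the exact binomial p was 0.046 as deposited and 0.18 after TMM scaling, so with so few genes the hypothesis stays open at a ratio of 0.62. As deposited, the microRNA gene Mir8104 was among the gained and Mir6972, Mir6979 and Mir324 among the lost. The test was not run without these short genes.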
